A study of Mus musculus with 4 samples.

How the data were processed

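Red cell precursors from mouse fetal liver were stained for TER119 and CD71 and sorted into 4 populations named R2, R3, R4 and R5, and RNA was taken from the sorted cells without culture. Per the labels' protocols, RNA enriched for polyadenylated transcripts was made into 1 library per population and sequenced on an Illumina (Solexa) instrument. The values are RPKM (reads scaled to the length of the gene and the size of the library), as the authors deposited them, 1 value per gene symbol for 19564 symbols with 2 decimals. Per the submitters' processing notes the genome build was mm9. The aligner, the counting program, the gene annotation and the length used as the denominator are not given in the sources used here. The files hold gene symbols and no coordinates, and the reference annotation at hand is of build GRCm38, so no coordinates are printed.

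The depth was worked out from the values. Several housekeeping genes with many pseudogene copies (among them Rps27, Gapdh, Rps13, Rpl23a, Rps12 and Sumo2) took values that were whole multiples of 1 number per library, as if reads had been counted over 1 or 2 bases only. That number, the RPKM of 1 read over 1 base, was 43.6 in R2, 39.0 in R3, 36.5 in R4 and 48.3 in R5, and implies about 23000000, 25600000, 27400000 and 20700000 reads. For R3 a first estimate gave 89.7% even counts over fitted genes, against 47.9% in R2, so the R3 unit was doubled, after which 47.1% were even. Countable bases could be fitted in this way for 296 genes, with lengths of up to 400 bases searched. For 241 of the 252 with an annotated exonic length they came to under 0.5 of that length, a share that the search limit partly fixes. Exonic length overstates the reads of those genes. Reads were estimated for 8727 of the 9942 genes past the filter from the fitted bases or, otherwise, from exonic length, and 138 genes were backed by under 30 reads in every library. An RPKM of 10 over 1 kb stands for 229.6 reads in R2, 256 in R3, 274 in R4 and 207 in R5. A value of 0 can come from few countable bases (Gapdh is listed at 0 in R3), so a listed 0 is not read as absence of the transcript, and the ratios of RPKM + 1 of such genes stay in the counts, the ranks and the list medians.

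Genes with at least 1 RPKM in at least 1 of the 4 samples were kept, 9942 in all. For each gene the log2 ratio of RPKM + 1 was taken for 4 comparisons, R5 against R2 for the whole course and R3 against R2, R4 against R3 and R5 against R4 for its 3 steps. A gene was counted as higher or lower at a 2-fold ratio or more. With 1 library per population there is no test across genes, and such counts describe these libraries. Before the data were examined, 35 gene lists were written down, for pathways, complexes and markers of other cell types. Their 851 entries were matched to the symbols in the files, 38 through an older symbol written with the list and 12 through a table of synonyms of the current mouse annotation, and 35 were not matched. The mesenchymal marker list had 0 measured members. The median log2 ratio of each list was placed among 10000 random lists of the same size drawn from the same 20 bins of mean expression. A percentile below 2.5 or above 97.5 is described as standing apart.

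The genes named were fixed by a rule before the data were examined. Among genes with at least 10 RPKM in at least 1 of the samples compared, these were the 12 highest and 12 lowest log2 ratios for R5 against R2 and the 5 highest and 5 lowest for each step. From each list the rule added the 4 members with the highest mean and the 2 highest and 2 lowest ratios, and all members of the globin, heme synthesis, iron, transcription factor and enucleation lists. Tfrc was given in every sample as a check on the labels. Some genes that the rule takes are not reported here. Genes that entered only once those backed by under 30 reads were left out were chosen after the values were seen, as were single list members named for a step.

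Alternatives set before the data were examined were pseudocounts of 0.1 and 5 RPKM, no filter, a filter of 5 RPKM, scaling each sample by the median of its ratios to the geometric mean over the 2745 genes with at least 5 RPKM in every sample, and removal of the globin genes with rescaling of the rest to a common sum. Leaving out genes backed by under 30 reads, and setting R5 against R3 with R2 not used, were added after seeing the data. Exonic lengths came from the GRCm38 annotation by symbol, for 16956 of the 19564 symbols.

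The steps were tested on simulated data, in which reads were drawn for 8683 genes with 200 genes changed by known folds. Both libraries of a comparison were drawn, with counting noise alone, from the values of the same library. The changed genes were at 10 RPKM or more, and every fold lay beyond the 2-fold limit. For R5 against R2 all changed genes were recovered (100% at the fold size with the lowest share), 0.0118% of unchanged genes were called, a list shifted by 1 on the log2 scale stood at percentile 100, and an unshifted list at percentile 21.96. The simulation held no globin shift and no variation between libraries. These shares check the steps and are not error rates of the real comparisons. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used.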

Results

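Messenger RNA was profiled in 4 populations of developing red blood cells taken from the fetal liver of midgestation mouse embryos. The cells were separated by 2 surface markers, the erythroid antigen TER119 and CD71, the transferrin receptor. R2 holds the least mature of these erythroblasts, R3 the basophilic ones, R4 mainly polychromatophilic and orthochromatophilic ones, and R5 the most mature ones together with reticulocytes, which have lost their nucleus. Each population gave 1 library, so no difference here has a replicate check and no p-value across genes is given. Values are RPKM, and ratios are on the log2(RPKM + 1) scale, which understates the change of low genes. The step size of the values implied about 23000000 reads for R2, 25600000 for R3, 27400000 for R4 and 20700000 for R5, so that 10 RPKM over 1 kb stood for 207 reads in R5 and 274 reads in R4. At 1 RPKM or more, 9761 genes were detected in R2, 8111 in R3, 6531 in R4 and 7410 in R5.

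A gene behind the sort gave a check on the labels. Tfrc, which encodes CD71, was at 52.1 RPKM in R2, 133 in R3, 74.4 in R4 and 32.8 in R5. Under every scaling Tfrc was higher in R3 than in R2, with log2 ratios of 1.34 as deposited, 2.19 with median scaling and 2.10 with globins removed, and lower in R5 than in R4, with -1.16, -1.53 and -1.36. Its place in R5 against R2 turned with the scaling, from -0.65 as deposited to 0.90 and 0.57, and that in R4 against R3 from -0.83 to 0.24 with median scaling.

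Globin transcripts made up 5.52% of the summed RPKM in R2, 59.4% in R3, 80.4% in R4 and 81.9% in R5. These sums count both Hba-a1 and Hba-a2, whose values were identical and which together held 4.55%, 47.5%, 65.7% and 70.1%. The shares would be lower if the same reads were credited to both. A large globin share lowers the RPKM of all other genes. The median gene stood at a log2 ratio of -1.65 in R5 against R2, -1.09 in R3 against R2, -0.77 in R4 against R3 and 0.27 in R5 against R4. With samples scaled by the median of gene ratios these medians were -0.42, -0.37, -0.06 and 0.07, and with the globin genes removed they were -0.68, -0.47, -0.34 and 0.18. Gene groups are therefore set against random gene lists of matched expression, which carry the same shift, and counts of group members past 2-fold are as deposited where no scaling is named. Of 8854 genes with at least a 2-fold range over the 4 populations as deposited, 8026 were highest in R2 and 6833 lowest in R4. The genes with such a range were drawn anew under each rescaling. The counts were then 2745 and 1701 with median scaling and 4501 and 3742 with globins removed. As deposited, only 28 of the 8854 genes were higher at every step, and 1170 were lower at every step. Across genes, which are not independent replicates, Pearson's r of log2 values was 0.855 between R2 and R3, 0.962 between R3 and R4, and 0.967 between R4 and R5. R5 stood closer to R2 than R4 did, with r of 0.846 against 0.772. By Spearman's rho R5 was the closest to R2, at 0.860, against 0.849 for R3 and 0.803 for R4.

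**Figure D1:**
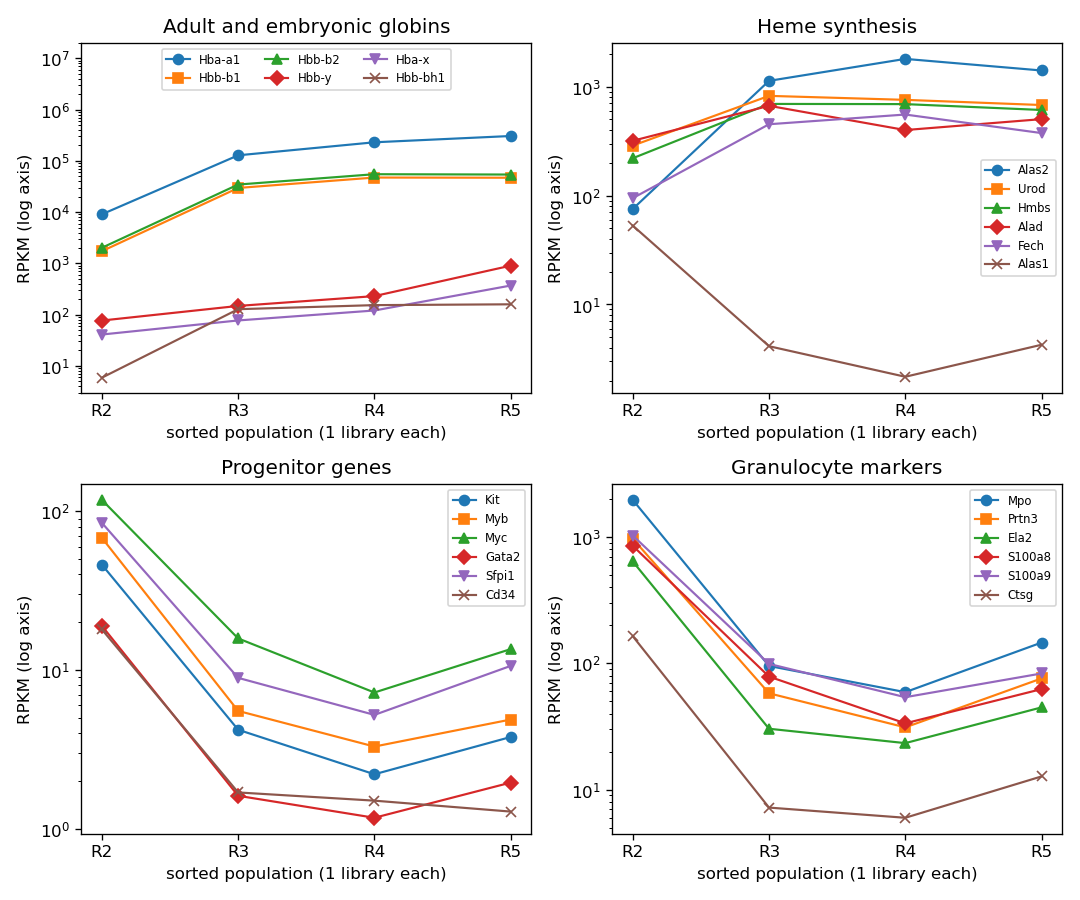
RPKM on a log axis in the 4 sorted populations, 1 library each and so without error bars, for globin, heme synthesis, progenitor and granulocyte genes. Alas2 went from 75.3 in R2 to 1797 in R4, while Alas1 went from 53.0 to 2.17 and Mpo from 1966 to 59.1.

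The comparison of R5 with R2 covers the whole course and asks which transcripts mark late against early erythroblasts. The late population carried the genes of the finished red cell: adult globins, Alas2, the rate-limiting enzyme of erythroid heme synthesis, and Slc4a1, the anion exchanger band 3. The early population was higher in progenitor genes, ribosome assembly genes and granulocyte genes. RNA of granulocyte-lineage cells in the R2 library is a candidate source of the granulocyte genes. Whether it also adds to the progenitor and ribosome assembly genes was not tested. Alpha-globin (Hba-a1) went from 9072 to 306178 RPKM, a log2 ratio of 5.08, and Hbb-b1 from 1731 to 46936, a ratio of 4.76. Alas2 went from 75.3 to 1406 RPKM, which was 18.7-fold, and Slc4a1 from 164 to 1734, a ratio of 3.40.

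All 8 measured globin genes were at least 2-fold higher in R5, with a median log2 ratio of 4.64 at percentile 100 of the random lists. Hba-a1 and Hba-a2 had identical values in every library, so their reads were not told apart, and Hbb-b1 and Hbb-b2 are similar enough that the split between them is uncertain. Of 10 heme synthesis genes, 5 were at least 2-fold higher and 1 lower, with a median of 0.95 at percentile 99.85. The lower one was Alas1, the housekeeping form of the enzyme that Alas2 encodes in red cells, at 53.0 RPKM in R2 and 4.27 in R5. Red cell membrane genes had a median of 1.14 at percentile 100, with 12 of 22 at least 2-fold higher and 2 lower as deposited, and 19 and 0 with median scaling. Epb4.9, a membrane skeleton protein also called dematin, went from 41.0 to 246 RPKM, while the water channel gene Aqp1 went from 110 to 24.9.

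Other groups also stood above the random lists. Erythroid ubiquitin genes stood 2.66 above the all-gene median at percentile 100, with 12 of 23 at least 2-fold higher and 6 lower as deposited, and 16 and 1 with median scaling. Among them Ube2l6 went from 35.1 to 343 RPKM and Trim10 from 28.0 to 275. Genes of cell cycle arrest had a median of 0.18 at percentile 100, with 5 of 17 higher and 5 lower as deposited, 10 and 0 with median scaling, and 10 and 2 with globins removed. Cdkn2d, an inhibitor of cyclin-dependent kinases, went from 9.07 to 87.8 RPKM, and Rbl2 from 7.95 to 1.08. Canonical histone genes had a median of 1.02 at percentile 100, and 29 of 55 were at least 2-fold higher and 0 lower, but 24 of the 55 were backed by under 30 reads in every library. As deposited, their median was 0.05 in R3 against R2, -0.07 in R4 against R3 and 1.11 in R5 against R4. It stood at percentile 100 of the random lists in each step. With median scaling the medians of these steps were 0.68, 0.67 and 0.84, and with globins removed 0.67, 0.35 and 0.9955. The rise thus lay in R5 against R4 as deposited, but was spread over the steps under either rescaling. Hist1h2bc went from 9.91 to 85.2 RPKM. The libraries were enriched for polyadenylated RNA, and how evenly that enrichment acted on histone transcripts was not tested. Bcl2l1, which encodes the survival protein Bcl-xL, went from 18.2 to 263 RPKM. The glucose transporter gene Slc2a1 went from 51.1 to 649, unlike most of its list, glycolysis. There 3 of 20 genes were at least 2-fold higher and 17 lower as deposited, and 3 and 5 with median scaling.

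In some groups that lay above the random lists the direction depended on the scaling. Mitosis genes had a median of -0.71 at percentile 99.99 as deposited, 0.80 with median scaling and 0.47 with globins removed. Of 36, 1 was at least 2-fold higher and 13 lower as deposited, 8 and 0 with median scaling, and 5 and 0 with globins removed. The higher one as deposited was Ube2c, which drives the exit from mitosis, at 131 RPKM in R2 and 446 in R5, while Mad2l1 was at 23.4 and 4.87. Autophagy genes had a median of -0.71 at percentile 100, 0.76 with median scaling and 0.45 with globins removed, and 3 of 35 were at least 2-fold higher and 12 lower as deposited, 13 and 1 with median scaling, and 10 and 2 with globins removed. Erythroid transcription factors had a median of -0.76 at percentile 98.55, 0.82 with median scaling and 0.47 with globins removed, and 3 of 22 were at least 2-fold higher and 9 lower as deposited, 10 and 2 with median scaling, and 8 and 4 with globins removed. The 3 higher ones as deposited were E2f2, which went from 31.1 to 145 RPKM, Nfe2 from 60.4 to 216 and Sox6 from 2.99 to 10.3. Klf1 was at 254 and 255 RPKM, and Gata1 at 120 and 90.5, a log2 ratio of -0.40 that was 1.18 with median scaling and 0.84 with globins removed, while Stat5a was at 33.0 and 2.54 and Bcl11a at 34.7 and 5.42.

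Progenitor genes were lower in R5, with a median of -2.46 at percentile 0, and 17 of 20 were at least 2-fold lower and 3 within 2-fold as deposited, while 12 were lower and 1 higher with median scaling. Kit, the stem cell factor receptor, went from 46.1 to 3.78 RPKM, Myb from 68.1 to 4.87 and Myc from 118 to 13.5. Among those 3 was Lyl1, at 105 and 114 RPKM. Ribosome biogenesis genes had a median of -2.77 at percentile 0, and 29 of 29 were at least 2-fold lower as deposited, 23 with median scaling and 28 with globins removed. Npm1 went from 592 to 61.3 RPKM and the nucleolar methyltransferase gene Fbl from 496 to 60.7. Splicing genes had a median of -2.24 at percentile 0 and DNA replication genes one of -1.98 at percentile 1.66. With median scaling these medians were -0.67 and -0.44, and the members at least 2-fold lower went from 37 to 6 of 38 splicing genes and from 36 to 0 of 38 DNA replication genes. With globins removed 21 and 6 were lower. Ribosomal protein genes had a median of -1.85 at percentile 0.335, which was 4.04 with median scaling and 2.58 with globins removed, and 13 of the 73 were backed by under 30 reads.

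Granulocyte marker genes moved with these lower groups. All 10 measured ones were at least 2-fold lower in R5, with a median of -3.60 at percentile 0. Mpo, which encodes myeloperoxidase, was at 1966 RPKM in R2 and 146 in R5, and S100a8 at 851 and 62.5. Lymphoid markers had a median of -2.24 at percentile 0.02 that was 5.08 over 3 members with a filter of 5 RPKM, and 5 of 5 were at least 2-fold lower as deposited and 2 with median scaling. Cd79b was at 10.7 and 1.47 RPKM. Sfpi1, a progenitor list member at 84.7 and 10.6 RPKM, also acts in granulocyte development. Hepatocyte markers had a median of 0.65 at percentile 100 and megakaryocyte markers one of 0.27 at percentile 100.

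Several groups did not stand apart from the random lists in R5 against R2. Iron handling genes had a median of -1.54 at percentile 59.2, with 2 of 18 at least 2-fold higher and 10 lower as deposited, 6 and 0 with median scaling, and 6 and 2 with globins removed. Within that list Slc25a37, the mitochondrial iron importer, went from 93.0 to 605 RPKM and the ferritin light chain gene Ftl1 from 1467 to 3905, while Trfr2, another transferrin receptor, was at 55.7 and 18.4, a log2 ratio of -1.55 that was 0.0017 with median scaling. Oxidative phosphorylation genes had a median of -1.43 at percentile 58.9, which was 0.13 with median scaling. Antioxidant genes had a median of -0.98 at percentile 97.2, which was 0.53 with median scaling and 0.21 with globins removed, and Gpx1, a glutathione peroxidase, went from 1720 to 6822 RPKM. Chromatin modifier genes had a median of -1.83 at percentile 35.4, genes of enucleation and chromatin condensation one of -1.64 at percentile 75.04, and genes of apoptosis one of -1.66 at percentile 52.0. Proteasome genes had a median of -1.90 at percentile 3.795, RNA polymerase II genes one of -1.95 at percentile 13.6, mitochondrial ribosome genes one of -1.98 at percentile 3.20, glycolysis genes one of -1.91 at percentile 6.04 and immediate early genes one of -1.86 at percentile 21.2.

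By the rule for named genes, the 12 highest ratios also held Hbb-bh1, an embryonic globin gene, at 4.54, Tmcc2, with 52.8 and 991 RPKM, F830116E18Rik at 3.96, Phospho1 at 3.90 and Ypel4 at 3.82. Hbb-bh1 stood at 0.340% of the Hbb-b1 value in R2 and 0.339% in R5, so reads shared with the adult gene are not excluded. Rnu12 was listed at 0 in R2 and at 19.3 RPKM in R5, where that value stood for 6 reads. At the low end, Rps27, Rps12, Snord32a and Gm10052 rested on under 30 reads in every library. BC100530 followed at -3.85, Ela2, which encodes neutrophil elastase, at -3.81, Stfa1 at -3.79, Fcnb at -3.76, S100a8 at -3.75, Mpo at -3.74 and Hp at -3.66. The next genes with enough reads were chosen after their values were seen, and were Prtn3 at -3.66, S100a9 at -3.61, Ctsg at -3.59, Rpl23 at -3.58 and Anxa1 at -3.57.

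In all, 272 genes were at least 2-fold higher in R5 than in R2 and 7643 lower, a split of 3.44% against 96.6% of calls. With median scaling 937 were higher and 1367 lower, or 40.7% against 59.3%, and with globins removed 730 were higher and 2961 lower, or 19.8% against 80.2%. With R2 not used, a choice made after seeing the data, 66 genes were higher and 1300 lower in R5 than in R3, and the medians of heme synthesis and membrane genes were -0.29 and -0.80. The sign or the side of the random lists also turned for progenitor genes (-0.029), mitosis (-1.01), cell cycle arrest (-0.28), ribosome biogenesis (-0.40), erythroid ubiquitin genes (-0.25) and granulocyte (-0.27) and lymphoid markers (0.16), and the sign for hepatocyte markers (-0.58).

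**Figure D2:**
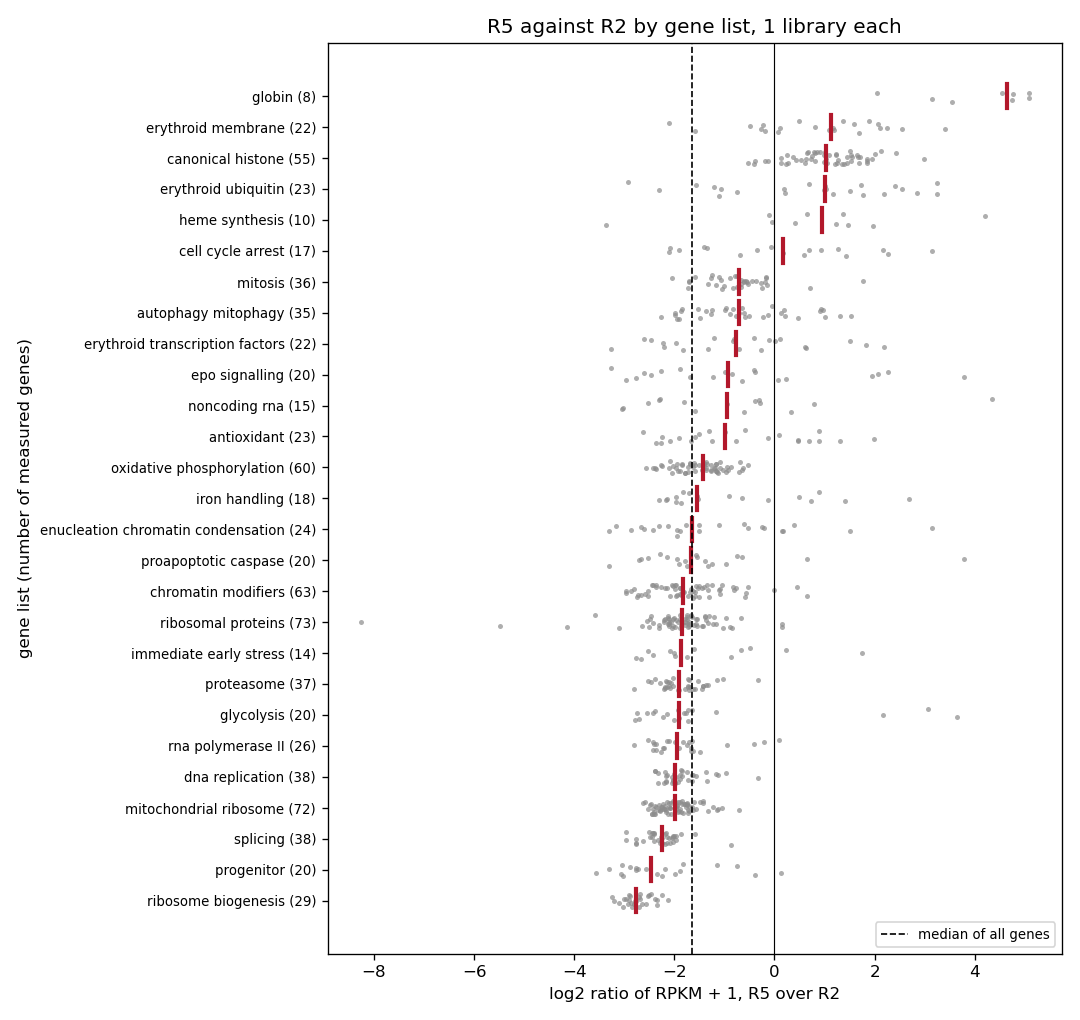
Log2 ratio of RPKM + 1 in R5 over R2, 1 library each, for the genes of 27 lists (grey points, 1 per gene) with each list's median (red bar) and the median of all genes (dashed line, -1.65). Globin genes have a median of 4.64 and ribosome biogenesis genes one of -2.77; the mitosis, autophagy, transcription factor, antioxidant and oxidative phosphorylation medians are below 0 as drawn and above 0 with median scaling.

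R3 against R2 asks what sets basophilic erythroblasts apart from their immediate precursors. Medians of globin, heme synthesis and membrane genes lay above the random lists in R3, and those of progenitor, ribosome biogenesis, glycolysis and immediate early genes below them. Of 8 globin genes, 6 were at least 2-fold higher and 2 within 2-fold, with a median of 3.82 at percentile 100. Hbb-b1 went from 1731 to 29661 RPKM and Hbb-b2 from 2017 to 34559, Alas2 from 75.3 to 1129, a ratio of 3.89, and Slc4a1 from 164 to 2342, a ratio of 3.83. Hbb-bh1 had the highest ratio among genes with enough reads, 4.23, but stood at 0.340% of the Hbb-b1 value in R2 and 0.430% in R3, so shared reads are not excluded here either.

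Of 10 heme synthesis genes, 8 were at least 2-fold higher in R3 and 1 lower, with a median of 1.58 at percentile 99.97. Fech, which inserts iron to form heme, went from 94.7 to 451 RPKM. Membrane genes had a median of 1.64 at percentile 100, with 15 of 22 higher and 0 lower. Erythroid transcription factors had a median of 0.30 at percentile 99.9, with 6 of 22 higher and 6 lower as deposited, 12 and 3 with median scaling, and 11 and 3 with globins removed. Mitosis genes had a median of 0.23 at percentile 100, with 4 of 36 higher as deposited, 22 with median scaling and 15 with globins removed, and 0 lower under each, and Mki67, a proliferation marker, went from 69.8 to 196 RPKM. DNA replication genes were not apart from the random lists, with a median of -0.51 at percentile 96.59 that was 0.34 with median scaling and 0.25 with globins removed. Slc25a37, the mitochondrial iron importer, went from 93.0 to 1035 RPKM.

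Progenitor genes had a median of -2.43 at percentile 0, with 17 of 20 at least 2-fold lower as deposited and 15 with median scaling, and Myb went from 68.1 to 5.52 RPKM. Ribosome biogenesis genes had a median of -2.41 at percentile 0, and 29 of 29 were at least 2-fold lower as deposited, 25 with median scaling and 27 with globins removed. Ribosomal protein genes had a median of -1.19 at percentile 0.13. Glycolysis genes had a median of -1.81 at percentile 0, and 14 of 20 were at least 2-fold lower and 3 higher as deposited, and 10 and 3 with median scaling. Ldha, lactate dehydrogenase A, went from 801 to 117 RPKM, while the glucose transporter gene Slc2a1 went from 51.1 to 419. Immediate early genes had a median of -2.29 at percentile 0, with Fos at 34.7 RPKM in R2 and 1.80 in R3.

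Of the markers of other cell types, those of granulocytes and lymphoid cells moved with these groups. Hepatocyte, macrophage and megakaryocyte markers lay above the random lists, the last 2 at percentiles 99.77 and 99.88. Granulocyte markers were lower in R3 in all 10 cases, with a median of -3.39 at percentile 0, and lymphoid markers had a median of -2.43 at percentile 0. The summed RPKM of the granulocyte markers was 6130 in R2 and 431 in R3. Among genes with enough reads the lowest ratios were those of Ela2 at -4.36, Mpo at -4.35, Ctsg at -4.33, Stfa1 at -4.09 and Prtn3 at -4.04. Hepatocyte markers had a median of 1.14 at percentile 100, with 10 of 15 at least 2-fold higher in R3, and Alb went from 64.8 to 161 RPKM. By rank alone Sumo2 stood at the high end and Gapdh, Rpl23a, Rps12 and Snord34 at the low end, all backed by under 30 reads. In all, 379 genes were at least 2-fold higher in R3 and 5477 lower, 6.47% against 93.5% of calls. The split was 833 against 1789, or 31.8% against 68.2%, with median scaling, and 776 against 2262, or 25.5% against 74.5%, with globins removed.

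**Figure D3:**
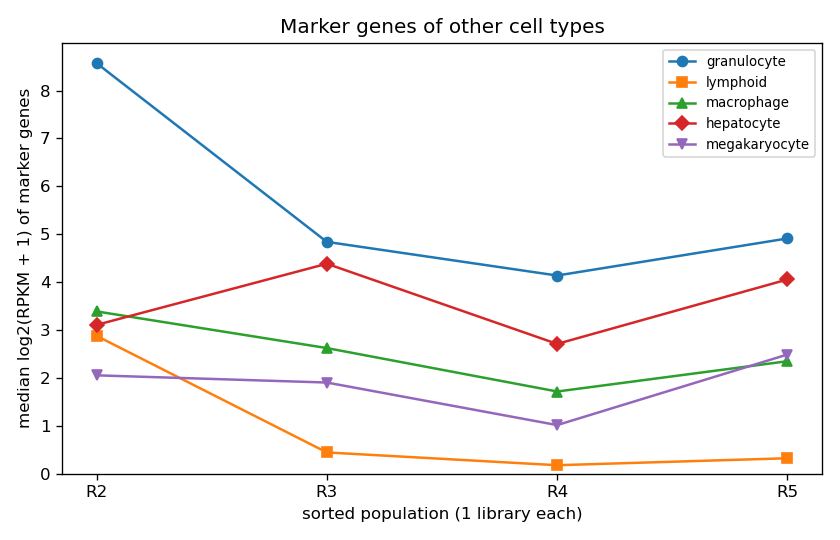
Median log2(RPKM + 1) of marker genes of 5 other cell types in the 4 sorted populations, 1 library each and so without error bars. The granulocyte median is 8.57 in R2 and 4.84 in R3, the hepatocyte median is 4.38 in R3 and 2.71 in R4, and the megakaryocyte median is 1.01 in R4 and 2.49 in R5.

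R4 against R3 asks what changes as basophilic erythroblasts become polychromatophilic and orthochromatophilic. Medians of DNA replication and ribosomal protein genes lay below the random lists, and 49 genes were at least 2-fold higher as deposited. Xpo7, a nuclear exporter, went from 30.1 to 146 RPKM, a log2 ratio of 2.24. Tmcc2 went from 503 to 1776, a ratio of 1.82, and Bpgm, which makes the hemoglobin regulator 2,3-bisphosphoglycerate, from 62.4 to 194, a ratio of 1.62.

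DNA replication genes had a median of -1.67 at percentile 0 that was -0.67 with median scaling, and 38 of 38 were at least 2-fold lower in R4 as deposited, 0 with median scaling and 24 with globins removed. Pcna, the sliding clamp of DNA polymerase, went from 651 to 162 RPKM and Mcm2 from 185 to 49.2. Ribosomal protein genes had a median of -1.43 at percentile 0 and splicing genes one of -1.32 at percentile 0, which were -0.38 and -0.28 with median scaling. Their members at least 2-fold lower went from 58 to 8 of 73 and from 32 to 0 of 38 with that scaling, and to 18 and 2 with globins removed. Mitosis genes were not apart from the random lists, at percentile 68.19, with 18 of 36 at least 2-fold lower as deposited and 0 under either rescaling, and their median was 0.02 with median scaling and -0.38 with globins removed. Erythroid ubiquitin genes had a median of 0.44 at percentile 100, with 5 of 23 at least 2-fold higher and 2 lower as deposited and 14 and 0 with median scaling. Ube2o, which tags proteins for removal in reticulocytes, went from 124 to 297 RPKM, and Trim58 from 23.5 to 64.6. Globin genes had a median of 0.65 at percentile 100, and 0 of 8 were at least 2-fold higher as deposited and 8 with median scaling.

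Membrane genes had a median of -0.27 at percentile 99.96 that was 0.80 with median scaling and 0.39 with globins removed. Autophagy genes had one of -0.46 at percentile 99.99 that was 0.50 and 0.13 under these scalings. Hepatocyte markers were lower in R4, with a median of -1.26 at percentile 0.265 and 11 of 15 at least 2-fold lower as deposited, 0 with median scaling and 2 with globins removed. Other genes with high ratios were Tcp11l2 at 1.74 and Ankrd43 at 1.63. Those with low ratios and enough reads were Stmn1, a microtubule regulator, at -2.65, Rpl22l1 at -2.51, Erh at -2.28 and Rpa3 at -2.21, while Snora65 had 8 reads in R3 and 1 in R4. By rank alone Gapdh and Rnu12 stood at the high end and Rps13, Rps27, Rpl11 and Snord32a at the low end, all backed by under 30 reads. In all, 49 genes were at least 2-fold higher in R4 and 3194 lower, 1.51% against 98.5% of calls. With median scaling the balance turned to 424 against 38, or 91.8% against 8.23%, and with globins removed it was 197 against 281, or 41.2% against 58.8%.

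R5 against R4 asks what marks the last stage, which includes reticulocytes. The embryonic globins Hbb-y and Hba-x were at least 2-fold higher in R5 than in R4. As a share of the Hbb-b1 value, Hbb-y was highest in R2, at 4.43%, with 0.499% in R3, 0.485% in R4 and 1.92% in R5. Medians of ribosomal protein genes, histone genes and markers of megakaryocytes and hepatocytes lay above the random lists, and those of red cell membrane and erythroid ubiquitin genes below them. The embryonic globin gene Hbb-y went from 230 to 903 RPKM, a log2 ratio of 1.97, and Hba-x from 120 to 370, a ratio of 1.61, while embryonic Hbb-bh1 was at 153 and 159, a ratio of 0.053, and adult Hbb-b1 at 47348 and 46936. Hbb-bh1 stood at 0.324% of the Hbb-b1 value in R4 and 0.339% in R5, so shared reads are not excluded for it. Pf4, a platelet chemokine gene, went from 7.04 to 31.6 RPKM, a ratio of 2.02.

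Ribosomal protein genes had a median of 0.79 at percentile 100, with 12 of 73 at least 2-fold higher and 3 lower as deposited and 6 and 4 with median scaling, and ribosome biogenesis genes one of 0.78 at percentile 100. Canonical histone genes had a median of 1.11 at percentile 100, and 30 of 55 were at least 2-fold higher, with the limits of reads and enrichment given above. Immediate early genes had a median of 0.92 at percentile 100, with Jun at 1.76 and 6.22 RPKM. Membrane genes had a median of -0.52 at percentile 0 and erythroid ubiquitin genes one of -0.46 at percentile 0, with 3 of 22 and 3 of 23 at least 2-fold lower and the others within 2-fold as deposited. With median scaling 8 and 8 were lower, and with globins removed 6 and 4. Heme synthesis genes had a median of -0.17 at percentile 1.14. Slc4a1 went from 2667 to 1734 RPKM, Slc25a37 from 1279 to 605 and Trim58 from 64.6 to 21.9.

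Megakaryocyte markers had a median of 1.28 at percentile 100, with 6 of 11 at least 2-fold higher, hepatocyte markers one of 0.87 at percentile 100, with 5 of 15 at least 2-fold higher as deposited and 2 with median scaling, and granulocyte markers one of 0.76 at percentile 99.4 that was 0.64 at percentile 97.2 with no filter. These moved beside the ribosomal, histone and immediate early groups. Transcript length moved with the ratio as well. Genes of up to 1483 bases of exonic length had a median ratio of 0.56 and those of 3726 bases or more one of -0.15, among genes at 10 RPKM or more in both libraries. Snora65, Rpl12 and Atp5g1 also ranked high, but R4 held 1, 3 and 6 reads of them against 12, 12 and 26 in R5. Clm3 was listed at 0 in R4 and at 12.1 RPKM in R5, with an unknown number of reads. The low end held Cpeb4 at -1.66, 1700023B02Rik at -1.59, Trim58 at -1.52, Atp2b4 at -1.51 and Xpo7 at -1.43. By rank alone Rpl23a, Rps13 and Hist1h2ai stood at the high end and Sumo2 at the low end, all backed by under 30 reads. In all, 394 genes were at least 2-fold higher in R5 and 60 lower, 86.8% against 13.2% of calls. The balance turned to 174 against 255, or 40.6% against 59.4%, with median scaling, and was 296 against 157, or 65.3% against 34.7%, with globins removed.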

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

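Leaving out genes backed by under 30 reads and not using R2 were tests chosen only after the results were seen; the other settings were planned. No paired analysis was possible because each population had 1 library and its replicate number only names it. Keeping the highest of several entries for a gene gave no value, since 0 symbols were duplicated. With 1 library each, no spread between replicates sets a scale for these shifts, and genes with few countable bases are limited by their reads. Of the 8 counts of genes past 2-fold, 8 stayed within 1.5 times with no filter, 8 with a filter of 5 RPKM, 4 with a pseudocount of 0.1, 1 with a pseudocount of 5, 1 with globins removed and 0 with median scaling. Of the list medians compared, 64 of 66 kept their side of the percentile limits, and their direction if they stood apart, with no filter, 61 of 64 with a filter of 5 RPKM, 63 of 66 with a pseudocount of 0.1, 62 of 66 with a pseudocount of 5, 56 of 66 with median scaling, 55 of 64 with globins removed and 64 of 66 without genes under 30 reads. With R5 set against R3 and R2 not used, 14 of 34 list medians did so. By construction both rescalings take out part of the fall in RPKM that globin reads impose; otherwise the cause was not tested.

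With a pseudocount of 0.1 RPKM, 74 genes were higher and 5880 lower in R4 against R3, and 1587 higher and 155 lower in R5 against R4. For R5 against R2, ribosomal proteins had a median of -1.85 (percentile 5.16) and noncoding RNAs one of -1.82 (percentile 76.7), both now inside the limits, and mast cell markers one of -3.06 (percentile 0.87), now outside. With a pseudocount of 5 RPKM, 4751 genes were lower in R5 against R2, 251 higher and 2969 lower in R3 against R2, 24 higher and 970 lower in R4 against R3, 79 higher and 21 lower in R5 against R4, and 5263 genes were highest in R2. Glycolysis at -1.67, antioxidant genes at -0.81, RNA polymerase II genes at -1.69 and mitochondrial ribosome genes at -1.66 then lay outside the limits for R5 against R2. With no filter, antioxidant genes at -0.98 (percentile 97.8) lay outside, and granulocyte markers in R5 against R4 at 0.64 (percentile 97.2) inside. With a filter of 5 RPKM, erythropoietin signalling at -1.38 (percentile 96.1), noncoding RNAs at -1.60 (percentile 85.8) and lymphoid markers at -2.34 (percentile 5.08) lay inside.

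With median scaling, genes higher and lower numbered 937 and 1367 in R5 against R2, 833 and 1789 in R3 against R2, 424 and 38 in R4 against R3, and 174 and 255 in R5 against R4, and 2745 genes were highest in R2 and 1701 lowest in R4. Among reported lists that stood apart, the sign turned in R5 against R2 for transcription factors (0.82), mitosis (0.80), autophagy (0.76) and endothelial markers (0.52), and in R4 against R3 for membrane genes (0.80) and autophagy (0.50). Ribosomal proteins at -0.25 (percentile 4.04), noncoding RNAs at -0.18 (percentile 77.5) and macrophage markers at -0.050 (percentile 96.2) then lay inside the limits, and mitochondrial ribosome genes at -0.54 (percentile 2.36) outside. Among lists inside the limits, antioxidant (0.53) and oxidative phosphorylation genes (0.13) turned in R5 against R2. Named genes past 2-fold that turned were Trfr2 (0.0017), Zbtb7a (0.33), Nfe2l1 (0.17), Setd8 (0.058) and H1f0 (0.41). Some named genes under 2-fold changed sign too, such as Tfrc (0.90), Gata1 (1.18) and Epor (1.19). With globins removed, genes higher and lower numbered 730 and 2961 in R5 against R2, 776 and 2262 in R3 against R2, and 197 and 281 in R4 against R3, with 157 lower in R5 against R4, and 4501 genes were highest in R2 and 3742 lowest in R4. Among reported lists that stood apart, the sign turned for transcription factors (0.47), mitosis (0.47), autophagy (0.45) and endothelial markers (0.33) in R5 against R2, and for membrane genes (0.39) and autophagy (0.13) in R4 against R3. Ribosomal proteins at -0.60 (percentile 2.58) and noncoding RNAs at -0.35 (percentile 89.1) lay inside the limits, mitochondrial ribosome genes at -0.86 (percentile 2.33) outside, antioxidant genes, inside them, turned (0.21), and Zbtb7a (0.0004) and H1f0 (0.078) turned.

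Without genes backed by under 30 reads, noncoding RNAs at -1.60 (percentile 68.1) lay inside the limits and antioxidant genes at -0.98 (percentile 97.6) outside. With R2 not used, 66 genes were higher and 1300 lower in R5 against R3, and 3000 genes were lowest in R4. Set against R3 in place of R2, the sign or the side of the random lists turned for heme synthesis (-0.29), membrane genes (-0.80), progenitor genes (-0.029), mitosis (-1.01), cell cycle arrest (-0.28), ribosome biogenesis (-0.40), erythroid ubiquitin genes (-0.25), granulocyte markers (-0.27), hepatocyte markers (-0.58) and lymphoid markers (0.16). Transcription factors (-0.79), ribosomal proteins (-0.65), noncoding RNAs (-0.31), macrophage markers (-0.26) and endothelial markers (-0.17) lay inside the limits. Iron handling (-0.98), glycolysis (0.017), antioxidant genes (-0.38), immediate early genes (0.53) and mitochondrial ribosome genes (-0.49) lay outside them.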

Other observations

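Tests chosen only after the result was seen were the removal of globins for the granulocyte list, the length trend over hepatocyte genes, and the tests of the embryonic globins against Hbb-b1, Hba-a1 and genes of similar length; the other tests were written before their result was seen.

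Erythropoietin signalling genes divided over the course. Their median log2 ratio in R5 against R2 was -0.92 at percentile 99.94 of the random lists, with 4 of 20 members at least 2-fold higher and 9 lower as deposited, 7 and 5 with median scaling, and 4 and 6 with globins removed. It was -0.034 with median scaling, and -1.38 at percentile 96.1 with a filter of 5 RPKM. Pim1, a survival kinase, went from 59.2 RPKM in R2 to 232 in R5, and Socs3, a feedback inhibitor of cytokine receptors, from 1.61 to 11.6. The signal transducer gene Stat5a went from 33.0 to 2.54 and the phosphatase gene Ptpn6 from 63.3 to 8.49, while Epor, the receptor itself, was at 144 and 109, a log2 ratio of -0.40 that was 1.19 with median scaling. Among genes tied to enucleation, Xpo7 was at 5.17 RPKM in R2, 146 in R4 and 53.4 in R5.

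Noncoding RNAs had a median of -0.94 at percentile 99.2 over 15 genes, and this place among the random lists was lost under several settings, such as percentile 77.5 with median scaling. Gas5, a host gene of small nucleolar RNAs, went from 81.7 RPKM in R2 to 9.19 in R5, and Malat1 was at 35.9 and 29.1, a log2 ratio of -0.29 that was 0.92 with globins removed. Macrophage markers had a median of -0.79 at percentile 99.86, which was -0.050 with median scaling, with Lyz2 at 212 and 20.7 RPKM and C1qc at 16.9 and 14.6, a log2 ratio of -0.20 that was 1.29 with median scaling. Endothelial markers had a median of -0.48 at percentile 98.985 over 5 genes, which was 0.52 with median scaling and 0.33 with globins removed. Mast cell and basophil markers had a median of -1.50 at percentile 10.2 over 6 genes, led by Prg2 at 138 and 12.5 RPKM. Of the 9 mesenchymal markers 0 reached 1 RPKM in any library.

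Granulocyte genes were far higher in R2 than in R3, with Mpo at 1966 and 95.2 RPKM. A scale effect of globin reads is argued against: with globins removed the list's median was still -2.62, with members from -3.58 to -1.92. RNA of granulocyte-lineage cells in the R2 library is a candidate source, since 20 of 20 genes of a second myeloid list were at least 2-fold lower in R3, with a median of -2.93 at percentile 0 where random lists had -1.13. Some genes of that second list are used by many blood cells, and a sort on TER119, an erythroid antigen, would remove granulocytes from any gate that requires it. Early erythroid cells that themselves hold such transcripts, as the maturation order of the populations would allow, were not tested and stay open.

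Long genes were lower and short genes higher in R5 than in R4. Counting noise is argued against, since among 1465 genes at 10 RPKM or more in both libraries Spearman's rho of the ratio with exonic length was -0.52, across genes, which are not independent replicates; in the earlier steps it was 0.18 and 0.24. Loss of RNA or fragments by length in the R5 library is a candidate explanation: over 33 hepatocyte genes, which erythroid maturation should leave in 1 ratio, rho was -0.43, and in the earlier steps -0.077 and -0.22. A change in which transcripts late erythroblasts and reticulocytes keep was not tested and stays open. The higher ribosomal protein and histone genes of R5, which are short, fall under the same doubt. The random lists were matched on expression and not on length, so the doubt extends to the other groups and genes named for this step. Among these are the membrane and erythroid ubiquitin genes, which were lower in R5.

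The embryonic globins Hbb-y and Hba-x were higher in R5 than in R4, at 903 against 230 and 370 against 120 RPKM. The embryonic globin Hbb-bh1 was at 159 against 153, but its value may hold reads shared with adult beta-globin. For Hbb-y, reads shared with adult beta-globin are argued against, since the ratio of Hbb-y exceeded that of Hbb-b1 by 1.98, and for Hba-x reads shared with adult alpha-globin as the whole cause, since its ratio exceeded that of Hba-a1 by 1.20. For the length trend, both genes were set against others of similar length. Among 65 genes outside the globin list of 518 to 780 bases, around the 633 of Hbb-y, and at 10 RPKM or more in both libraries, the median ratio was 0.65 and 0 reached that of Hbb-y. Among 102 such genes of 641 to 1001 bases, around the 801 of Hba-x, the median was 0.63 and 1 reached it, so Hba-x stood at percentile 99.0. Both ratios thus lay above the usual one for that length. The rank cannot decide whether the trend is the whole cause, since both genes were singled out for their high ratios. At least part of each ratio may come from the trend. RNA of primitive erythroid cells from the yolk sac, which carry these globins, could not be decided: Aqp3 and Aqp8, water channels of such cells, had a mean ratio of 0.26, with Aqp8 at 0.55 and 0.87 RPKM. That source and a late rise of these genes in definitive cells both stay open.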
